A study of Mus musculus with 14 samples.

How the data were processed

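RNA sequencing was measured in 14 libraries from the carotid arteries of C57BL/6 mice, 10 weeks old, per the labels. The lumen of each artery was flushed with 150 µL of Qiazol to collect an endothelial-enriched RNA fraction, and a second RNA fraction was extracted from the artery that was left over. Per the labels, the endothelial fraction had 4 littermate control and 4 endothelial knockout libraries, and the left-over fraction had 2 control and 4 smooth muscle knockout libraries. The design text of the series names 4 knockout and 4 control mice, so the 2 left-over controls are fewer than that text gives. The labels call the libraries of a group numbered repeats and say nothing further about what they repeat. Each library was treated as 1 sample.

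The deposited table held 35275 genes by Ensembl identifier, and no identifier occurred more than once. It gave raw read counts per gene and library, which the authors made by read alignment and gene counting. Per the submitters' processing notes, TopHat, STAR 2.5, HTSeq 0.6.1, DESeq2, edgeR 3.16.5 and STAR-Fusion were used, with no order or role stated. The table also gave FPKM values, which the authors scaled to the gene length and the library's summed counts. All nonzero FPKM values (100%) equalled the count divided by gene length and column total within a relative tolerance of 0.001. The authors also deposited the mean FPKM of 4 groups of libraries, log2 fold changes between those groups, and p-values and adjusted p-values for them. Other values in the deposited table were the gene length in bases, as the authors gave it, and gene coordinates. The tool behind the deposited log2 fold changes is not stated. The submitters' processing notes name the genome build mm9, but the coordinates in the table are those of GRCm38. Of the identifiers, 34490 (97.8%) were in GENCODE M21, and 97.6% of those had starts within 5 kb of the annotated start. The strandedness of the libraries is not given in the sources used here.

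The counts were used for every comparison made here. Library depth ran from 15019891 to 23287155 counts, and between 23906 and 30145 genes had at least 1 count. The count of 3 that a zero allows at 95% confidence corresponds to 0.129 to 0.1997 CPM, the counts of a gene scaled to a common library total, depending on the library. Such floors cover counting error only. The 10 genes with the most counts took 6.25 to 9.33% of each library, and mitochondrial genes took 0.176 to 0.951%. No pair among the 14 libraries, within or across groups, looked like a duplicate, the smallest chi-square per degree of freedom being 8.79. All 14 libraries had the expression of male mice, so sex was not used as a covariate.

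Groups were taken from the labels. The left-over libraries are called "labelled control" and "labelled knockout" throughout, since the deposited table's own group means place them differently. Its Ctrl_SM column equalled the mean of the 4 libraries labelled knockout in all of the 14805 genes at 1 FPKM or more (100%, tolerance 1e-06). Its PD2KO_SM column equalled the mean of the 2 libraries labelled control in 1 of 14498 genes, so that column is not their mean alone. Were it a mean of 4 libraries that included both labelled control, 4 times its value would fall below their sum in no gene, and it fell below in 0 of 30611 genes. For the 12 other libraries, each taken alone, it fell below in 2.94 to 8.44% of genes. As a mean of 4, the column can therefore hold both libraries labelled control, with others that were not analysed here, and none of the 12. This check was chosen after seeing the data.

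The comparisons were 4: endothelial knockout against control, left-over labelled knockout against labelled control, endothelial against left-over fraction in the libraries labelled control, and the difference of the knockout effects between the fractions. The first 3 were fitted on their own libraries and the last on all 14. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and counts were scaled by TMM. The test was the two-sided quasi-likelihood F test of edgeR 4.0.16 with robust dispersions, under limma 3.58.1, statmod 1.5.0 and R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 CPM used a prior count of 2. Within a fraction, Poldip2 and each list's mean log2 CPM were also compared by exact two-sided permutation tests, for which the smallest possible p was 0.0286 in the endothelial fraction and 0.0667 in the left-over fraction. The latter design cannot reach 0.05.

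The genes named from each comparison were chosen by a rule. Among called genes with a mean CPM of at least 1 and no overlap between the libraries of both groups, the 10 with the highest and the 10 with the lowest log2 fold change were named, without unnamed gene models. Where fewer than 10 genes passed, those with the smallest p up to 10 were named as not passing. For each list, up to 4 called members were to be named. Members and genes named beyond these rules were chosen after their values were seen.

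There were 29 gene lists, fixed with the gene rule, the comparisons and most alternatives before the data were examined. Markers of cell types covered endothelium, smooth muscle contractile genes, adventitial fibroblasts, adipocytes, macrophages, lymphocytes, erythroid cells, platelets and neutrophils, skeletal muscle, Schwann cells and neurons, and thyroid and parathyroid. Lists for metabolism covered NADPH oxidase and antioxidant genes, protein lipoylation with Clp protease and the TCA cycle, oxidative phosphorylation subunits, mitochondrially encoded genes, and glycolysis and hypoxia response. Lists for vascular function covered endothelial inflammatory response, interferon response, extracellular matrix and elastic fibre, endothelial junctions, and vasoactive and shear-responsive genes. The rest were cell cycle and DNA replication, autophagy, immediate early and dissociation stress, integrated stress and unfolded protein response, circadian clock, neighbours of Poldip2, and sex genes, the last kept as a check without a test. The result of 1 further list is not reported here, although it counts in the adjustment and in the numbers of lists called. The 28 other lists were tested by camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison with at least 5 tested members. Camera with an estimated correlation and fry were the alternatives. In camera a list is compared with the other genes, whereas fry asks whether its own members move on balance.

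The alternatives fixed beforehand were size factors of DESeq2 in edgeR, library size only, no filter on low counts, a filter at 1 CPM, DESeq2 1.42.0 as the tool, all 14 samples in one fit, the replicate number as a block, omission of each library in turn, the smooth muscle and adipocyte scores as covariates, the knockout groups in place of the controls for the fraction comparison, and limma voom with the library code as a random block. Alternatives chosen after seeing the data were the left-over labels exchanged, the fibroblast score or the clock phase score as a covariate, omission of the 2 endothelial libraries with the most fibroblast RNA, and the libraries labelled knockout as the left-over side of the fraction comparison. The clock phase score is log2 CPM of Dbp minus Arntl.

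Replicate numbers were checked for pairing. Across genes, libraries of the same number in the endothelial groups correlated at r from -0.397 to 0.298 after group means were removed, and 1 of 4 pairs was over 0.1. The left-over pairs gave 0.0166 and 0.211, and the 3 pairs of libraries that share a code between the fractions gave 0.0877 to 0.244, 2 of them over 0.1. Among the libraries labelled knockout, the one with the same code had the highest r for endothelial controls 1 (0.105), 2 (0.244) and 3 (0.0877). The next highest were -0.0104, 0.224 and 0.0525. However, labelled knockout 4 correlated more with control 4 (0.193), and labelled knockout 2 with control 2 (0.224). These values do not settle whether codes are pairs. Neither numbers nor codes were used as pairs in the main fits, which took the 14 libraries as independent samples. The code as a random block was among the alternatives. If a code stands for 1 mouse, those 3 pairs are not independent. The whole procedure was tested on simulated data with log2 changes of 1 and 2 put into 200 genes. It recovered 68% and 90% of them in the endothelial comparison, 44% and 92% in the left-over comparison, 63% and 87% in the fraction comparison, and 45% and 65% for the difference of effects. False calls were 7.06%, 7.48%, 3.85% and 4.35% of the calls, in that order. The changed genes were drawn only from those above a set mean count. Each gene was simulated independently, so variation shared by many genes, as from cell makeup, was not covered.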

Results

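The data were read counts per gene from 14 carotid artery libraries of mice in which Poldip2 was to be deleted in the endothelium or in smooth muscle. Poldip2 encodes polymerase delta interacting protein 2, a partner of DNA polymerase delta that also binds NADPH oxidase 4 and is found in mitochondria. The endothelial fraction comprised 4 control libraries of 19310531, 19708533, 18267924 and 23287155 counts and 4 knockout libraries of 21386786, 22483607, 22410093 and 20894125 counts. The left-over fraction, the artery without its flushed lining, comprised 2 libraries labelled control of 19559825 and 17728632 counts and 4 labelled knockout of 15900440, 15019891, 16411702 and 19733086 counts.

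Poldip2 (ENSMUSG00000001100) lies on the + strand of chromosome 11 from 78512193 to 78522736 in GRCm38. In the endothelial fraction its RNA was 41.2, 39.3, 42.4 and 52.1 CPM in controls 1 to 4 and 31.3, 21.7, 22.6 and 18.9 CPM in knockouts 1 to 4. The means were 43.7 ± 5.70 CPM (SD, n = 4) and 23.6 ± 5.36 CPM (SD, n = 4), so the knockouts held 54.0% of the control level. In the left-over fraction the order was the opposite under the labels. The 2 libraries labelled control held 32.6 and 27.7 CPM (mean 30.1 ± 3.51, SD, n = 2), and the 4 libraries labelled knockout held 64.5, 59.998, 83.7 and 86.8 CPM (mean 73.7 ± 13.4, SD, n = 4), 245% of the labelled control. These Poldip2 values were scaled within each fraction, so they are not compared between the fractions here.

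**Figure D1:**
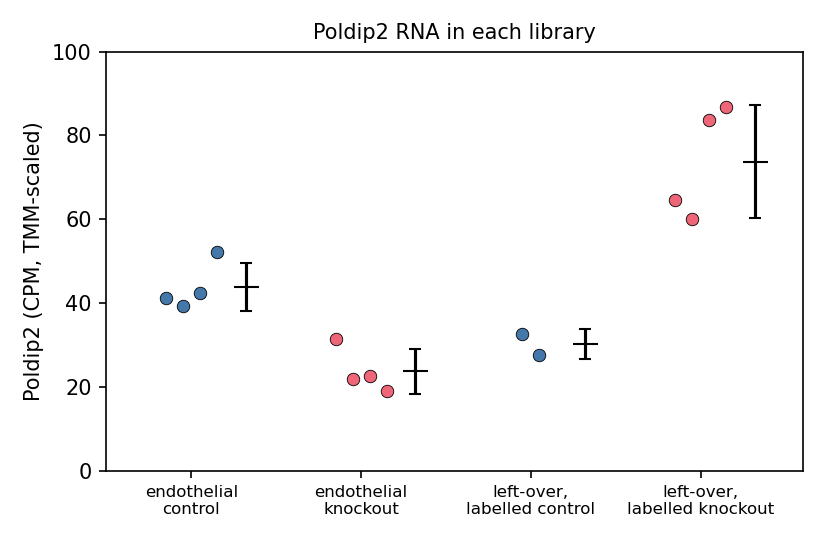
Poldip2 RNA in CPM (vertical axis, linear from 0) in each of the 14 libraries, 1 point per library, with the mean and 1 SD of each group beside the points. The 4 endothelial knockouts sit between 18.9 and 31.3 CPM, under all endothelial controls, while the 4 left-over libraries labelled knockout sit between 59.998 and 86.8 CPM, over both libraries labelled control.

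The endothelial difference in Poldip2 was a log2 fold change of -0.89 (SE 0.16), with no overlap between the groups. It did not pass over all genes (edgeR adjusted p = 0.270), and the exact permutation test gave p = 0.0286, the smallest it can give with 70 arrangements. DESeq2 gave -0.88 with an adjusted p of 5.3e-04, and omission of endothelial knockout 1 gave an edgeR adjusted p of 0.0377; over all the alternatives the adjusted p ran from 5.3e-04 to 0.847. In the left-over fraction Poldip2 was 1.29 higher on the log2 scale (SE 0.20) in the libraries labelled knockout (edgeR adjusted p = 0.00886). The exact permutation test gave p = 0.0667, the smallest it can give with 15 arrangements, and without labelled control 2 the log2 fold change was 1.17 and the edgeR adjusted p 0.110. In the authors' deposited table, mean Poldip2 was 21.1 FPKM in the endothelial control group, 11.6 in the endothelial knockout group, 35.9 in the smooth muscle control group and 12.7 in the smooth muscle knockout group. The 35.9 FPKM of that smooth muscle control group is the mean of the 4 libraries labelled knockout, and the libraries labelled control had a mean of 14.3 FPKM. The left-over knockout comparison reported here follows the labels, and each of its directions would be the opposite with the labels of these 6 libraries exchanged.

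The first comparison asked which RNAs the flush separated from the rest of the artery, in the libraries labelled control of both fractions. With the left-over labels exchanged, its left-over side would be 2 smooth muscle knockout libraries. Genes of endothelial identity were higher in the flushed fraction. Pecam1, an adhesion receptor of endothelial junctions, had 7024 ± 269 CPM (SD, n = 4) against 410 ± 170 CPM (SD, n = 2) in the left-over libraries labelled control. Edn1, the precursor of the vasoconstrictor endothelin 1, had a log2 fold change of 5.19, and Nos3, the endothelial nitric oxide synthase, 4.09. Genes of smooth muscle contraction were higher in the left-over artery. Acta2, smooth muscle alpha-actin, had 5265 ± 120 CPM (SD, n = 2) there against 194 ± 44.4 CPM (SD, n = 4) in the flushed fraction, and Myh11, smooth muscle myosin heavy chain, had a log2 fold change of -6.59.

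By list, all 20 endothelial markers were higher in the flushed fraction with a median log2 fold change of 4.03 (camera adjusted p = 5.4e-09; adjusted p = 0.388 with an estimated correlation). The estimated correlation left even these markers uncalled, so between the fractions it cannot tell a list that differed from one that did not. Of 16 smooth muscle contractile genes, 14 were lower and 1, Synm, was higher by 0.40, with a median of -4.57 (1.8e-06; 0.324 with an estimated correlation). All 15 adventitial fibroblast markers were lower (median -3.83), as were all 12 tested macrophage markers (median -4.56) and all 12 adipocyte markers (median -5.98), with estimated-correlation adjusted p of 0.628, 0.639 and 0.628. Among those, the proteoglycan gene Lum fell by 5.73, the complement gene C1qa by 5.13 and the lipid droplet gene Plin1 by 6.67. Thyroid markers were also lower in the flushed fraction, 4 of 5 passing with a median of -2.17 (adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone, the counts were the same for each of these lists.

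Genes that tie endothelial cells to each other were also higher in the flushed fraction. Of 16 junction genes 13 were higher, with Gja5 at 4.34, Cdh5 at 4.18 and Ocln at 4.13, and 2, Gja1 and Jam3, were lower (median 2.56; camera adjusted p = 3.8e-04; 0.388 with an estimated correlation). The endothelial inflammatory list had 12 higher and 3 lower of 16, the adhesion molecules Selp (4.21) and Vcam1 (4.10) on one side and the chemokine Ccl2 (-5.12) on the other (0.0261; 0.639 with an estimated correlation). Oxidative phosphorylation subunits were lower in 17 of 22 (median -0.48; 0.00113; 0.728 with an estimated correlation), and the NADPH oxidase and antioxidant list had 13 lower and 2 higher of 19 (median -0.76; 0.0224; 0.388 with an estimated correlation). Immediate early and dissociation stress genes were higher in 8 of 16, with Hspa1a at 3.98 and Jun at 1.88 (0.0257; 0.680 with an estimated correlation). Adjusted over the list alone, these counts were the same.

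**Figure D2:**
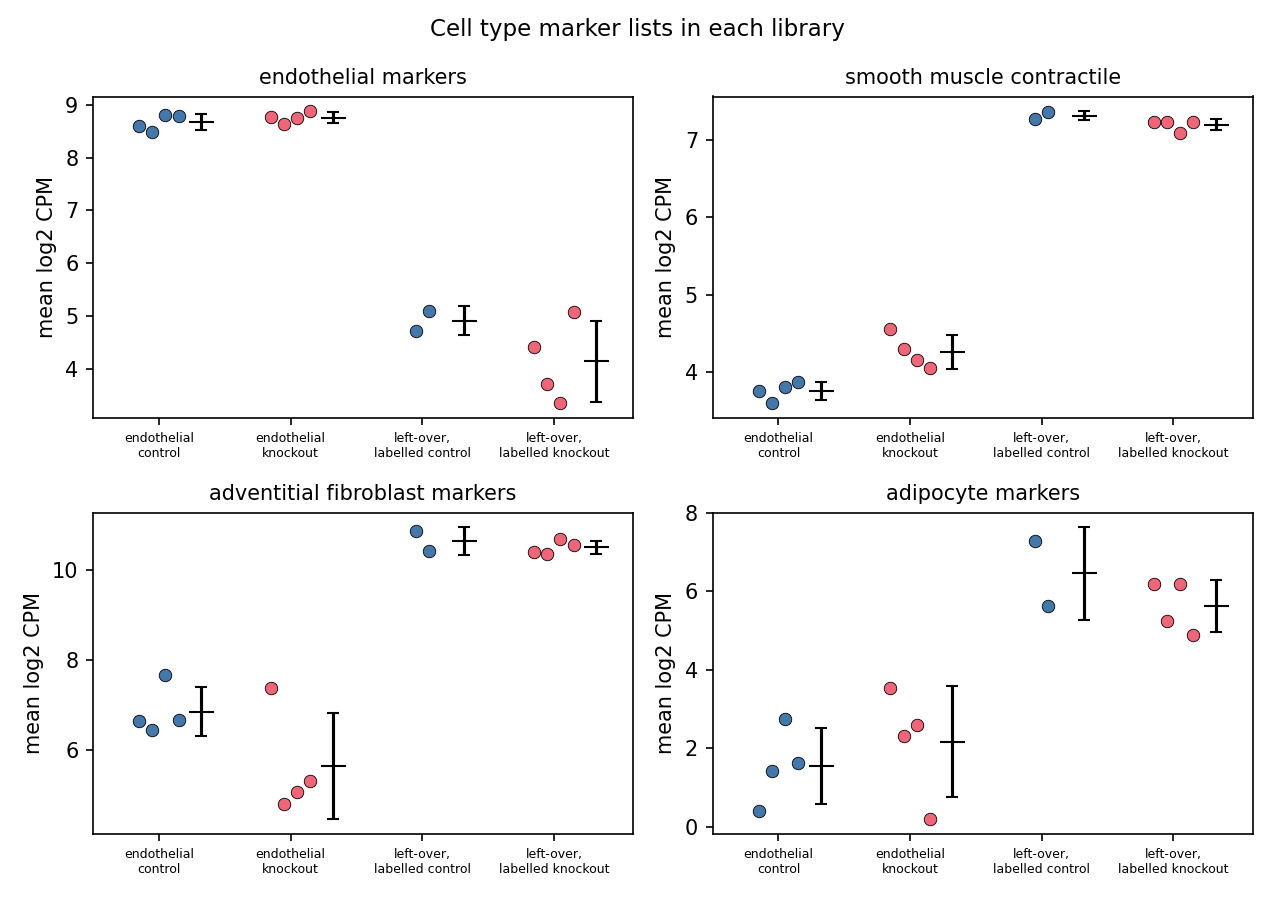
Mean log2 CPM of 4 cell type marker lists (vertical axes, each with its own range, not starting at 0) in each library, 1 point per library, with the mean and 1 SD of each group. Endothelial markers sit between 8.49 and 8.88 in the flushed libraries and between 3.35 and 5.10 in the left-over libraries, and the smooth muscle list is higher in all 4 endothelial knockouts (mean 4.26) than in all 4 endothelial controls (mean 3.76).

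In all, 12149 of 18484 genes tested (65.7%) were called by edgeR between the fractions, 6393 higher and 5756 lower in the flushed fraction, and 8029 of them differed by more than a log2 fold change of 1. The highest named genes were Stra6 (6.21), Mycn (6.18), Ptprr (5.81), Thbs1 (5.63), Nrarp (5.51), Dll1 (5.42), Rnf39 (5.36), Lsr (5.31), Sdcbp2 (5.30) and Acer2 (5.22), where Dll1 is a Notch ligand and Nrarp a Notch target. The lowest included Fmod (-7.61), Hspb7 (-7.40), Susd5 (-7.30), Pex5l (-7.06), Ndufa4l2 (-6.90) and Thrsp (-6.90). Tcap had 2 to 16 counts per endothelial library against 850 and 3232 in the left-over libraries. Igfbp2 had 1 count in each endothelial library against 252 and 176, Mogat1 had 0 or 1 against 157 and 51, and Gpihbp1 had 0 to 3 against 209 and 161. Poldip2 was 0.89 higher in the flushed fraction (adjusted p = 5.2e-04), against the 2 left-over libraries labelled control. Were their labels exchanged, this difference could not be told apart from the deletion of Poldip2 in smooth muscle. The authors' deposited table used other left-over libraries, the 4 labelled knockout, as its smooth muscle control group, and gave 0.36 for that group over its endothelial control group (adjusted p = 0.0813).

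The split of this count depended on scaling. With library size only it was 4650 higher and 7597 lower (38.0% higher against 52.6%), as the median of all genes moved from -0.05 to -0.38. With the 4 left-over libraries labelled knockout in place of those labelled control, 13404 genes were called, 10755 of them shared. Stra6 was not called without labelled control 1 (adjusted p = 0.122) or without labelled control 2 (0.108), and the oxidative phosphorylation and immediate early lists were not called without labelled control 1.

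The endothelial knockout comparison asked what differed in the flushed fraction when Poldip2 was deleted in the endothelium. Its clock phase scores were -2.51, -2.99, -0.15 and 1.90 in controls 1 to 4 and 4.53, 0.69, 0.50 and 0.84 in knockouts 1 to 4. Only control 4 lay above any knockout, so the main fit did not separate genotype from clock phase. No gene passed the test, and the genes with the smallest p included matrix and growth factor receptor genes with lower values in the knockouts. Spon2, which encodes the secreted matrix protein spondin 2, had 2.21 ± 0.420 CPM in controls and 0.508 ± 0.168 in knockouts (SD, n = 4 each). Fbn1, which encodes fibrillin 1 of elastic microfibrils, had 172 ± 34.5 and 86.8 ± 8.16 CPM. Egfr, the epidermal growth factor receptor, had 11.5 ± 4.81 and 3.35 ± 0.761 CPM. On the other side, Myh11 had 6.28 ± 1.90 CPM in controls and 19.4 ± 5.70 in knockouts, and Plek2, a pleckstrin family gene, had 80.4 ± 9.84 and 128 ± 10.98 CPM. The mean score of the adventitial fibroblast list was 6.86 in controls and 5.64 in knockouts, with overlap. That of the smooth muscle list was 3.76 and 4.26, without overlap. For the genes above, an effect in endothelial cells cannot be told apart from a different content of such other cells.

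The 10 genes with the smallest p were Spon2 (log2 fold change -2.11), Fbn1 (-0.98), Plek2 (0.67), Ptp4a3 (0.68), Igsf10 (-1.76), Otogl (-0.92), Lama2 (-1.45), Egfr (-1.78), Zbtb46 (0.50) and Myh11 (1.63). Their adjusted p ran from 0.227 to 0.270. Under the alternatives other than omission of 1 library, 31 results for these 10 genes passed and 79 did not. Without endothelial knockout 1, Igsf10 passed with an adjusted p of 0.0377, and without endothelial control 4, Fbn1 passed with 0.0400; neither passed in the other 7 omissions. In the authors' deposited table, Fbn1 was -0.81 (adjusted p = 2.9e-06), Igsf10 -1.07 (2.9e-06), Myh11 1.02 (7.5e-06) and Spon2 -1.04 (9.9e-06).

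Smooth muscle contractile genes were higher in the endothelial knockouts as a list (median 0.63, 12 of 15 positive; camera adjusted p = 8.1e-06; 0.365 with an estimated correlation). No member passed over all genes, and 6 passed adjusted over the list alone, namely Myh11, Cnn1 (1.502), Tpm2 (1.20), Myl9 (1.03), Actg2 (1.03) and Acta2 (0.67). The mean log2 CPM of the list was 3.76 ± 0.12 in controls and 4.26 ± 0.22 in knockouts (SD, n = 4 each), and 7.31 in the left-over libraries labelled control. Between the endothelial groups the exact permutation p was 0.0286, the smallest possible, and 0.414 adjusted over the list scores of the endothelial fraction. Endothelial markers were not called (median 0.08; adjusted p = 0.215). Adipocyte markers were positive in 11 of 11 (median 1.11; 0.0515).

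Adventitial fibroblast markers were lower as a list (median -0.87, 12 of 15 negative; camera adjusted p = 8.5e-08; 0.633 with an estimated correlation), and Cd248 (-1.93) passed adjusted over the list alone. Endothelial control 3 and endothelial knockout 1 had the highest fibroblast scores, 7.67 and 7.38 in mean log2 CPM, and knockouts 2 to 4 had 4.81, 5.07 and 5.31. The extracellular matrix and elastic fibre list was lower (median -0.05; 0.00915; 0.633 with an estimated correlation), with Fbn1 and Loxl1 (-0.72) passing adjusted over the list alone. Its call ended without endothelial control 4 and without endothelial knockout 3. Macrophage markers were lower by the test (0.0110; 0.671 with an estimated correlation) and by their mean (-0.14), but their median was 0.20. That call ended without endothelial control 3 or 4 and without knockout 2, 3 or 4. Exact permutation tests of the list scores gave p = 0.114 for fibroblast markers, 0.114 for the matrix list and 0.371 for macrophage markers.

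Mitochondrially encoded genes were lower in the endothelial knockouts, with 11 of 11 negative and a median of -0.44 (camera adjusted p = 4.4e-07; 0.633 with an estimated correlation). Of them mt-Nd2 (-0.64), mt-Nd4 (-0.64) and mt-Cytb (-0.47), subunits of respiratory complexes, passed adjusted over the list alone and 0 passed over all genes. The nuclear-encoded oxidative phosphorylation subunits were positive in 21 of 22 with a median of 0.08 (0.00240; 0.671 with an estimated correlation). The lipoylation, Clp protease and TCA cycle list was positive in 18 of 21 with a median of 0.08 (0.00263; 0.633 with an estimated correlation), and its call ended without knockout 2. Of the vasoactive list, Nos3 (0.38) and Ptgis (0.36), the prostacyclin synthase, passed adjusted over the list alone, and the list was not called (0.526).

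Over all genes, edgeR called 0 of 14800, 917 had an unadjusted p under 0.05, and the smallest adjusted p was 0.227. DESeq2 called 69 genes, 25 higher and 44 lower, and the authors' deposited table called 56, 23 higher and 33 lower. Without endothelial knockout 1 edgeR called 20 genes, and with the fibroblast score as a covariate it called 113. Without both libraries highest in fibroblast markers it called 97, of which 94 were lower. In that setting every remaining control had a higher fibroblast score (at least 6.44 in mean log2 CPM) than every remaining knockout. Fibroblast content and genotype therefore coincided there. The deposited log2 fold changes and those computed here correlated at r = 0.872 across 14800 genes, which are not independent replicates.

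The left-over comparison was meant to show the effect of deleting Poldip2 in smooth muscle, and is given here as labelled. Its groups also differed in clock phase score, -5.38 to -4.17 in the libraries labelled knockout against 0.70 and 4.37. Effects of the labelled genotype and of that difference cannot be told apart in it. Members of the stress response list rose and most called members of the clock list fell in the 4 libraries labelled knockout, 6 of 18 and 7 of 15 genes. Hspa8, the constitutive cytosolic chaperone, had 735 ± 106 CPM (SD, n = 2) in the libraries labelled control and 3371 ± 707 CPM (SD, n = 4) in those labelled knockout. Cdkn1a, the cell cycle inhibitor p21, had 44.4 ± 5.20 and 195 ± 29.7 CPM. Dbp, a transcription factor driven by the circadian clock, had 93.3 ± 66.7 and 2.72 ± 0.708 CPM. Nr1d2, a clock repressor of the nuclear receptor family, had 211 ± 64.2 and 41.0 ± 5.33 CPM.

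Of the integrated stress and unfolded protein response list, 6 of 18 genes rose and 0 fell (median 0.68; camera adjusted p = 5.6e-07; 0.568 with an estimated correlation), and 7 rose adjusted over the list alone. The 6 were Hspa5 (1.66), the chaperone BiP of the endoplasmic reticulum, Dnajb9 (1.32), Herpud1 (1.31), Ddit3 (1.15), Xbp1 (1.07) and Atf4 (0.93), the last 3 being transcription factors of these responses. Hspa5 ran from 1.19 without labelled control 2 to 2.34 without labelled control 1, and its call ended in 4 of the 6 omissions. Outside the list, the chaperone genes Hsph1 (3.12) and Dnaja1 (1.74), the endoplasmic reticulum stress factor Manf (2.21), the mitochondrial folate enzyme Mthfd2 (2.30) and the glucocorticoid-inducible cochaperone Fkbp5 (1.93) rose. From other lists Dnajb1 (1.23), a cochaperone, Klf4 (0.94), a shear-responsive transcription factor, and Cdkn1a (2.14) were the single genes that rose. Among the genes named by the rule were also Spon2 (2.31) and Banp (1.80), which rose.

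Of the circadian clock list, 7 of 15 genes fell and 1 rose (median -1.42; camera adjusted p = 2.6e-04; 0.568 with an estimated correlation), and 8 fell and 2 rose adjusted over the list alone. Dbp (-5.10), Ciart (-4.09), Nr1d2 (-2.36), Tef (-2.17), Hlf (-2.11), Bhlhe41 (-1.79) and Per3 (-1.42) fell, and Cry1 (1.43) rose. Without labelled control 2, Ciart was -2.21 and not called (adjusted p = 0.195), and its call ended in 5 of the 6 omissions of 1 library. With 1 library omitted Dbp ran from -5.69 to -4.09, losing its call in 3 of the 6 omissions, and Hlf from -2.52 to -1.54. Arntl, the partner of Clock in the activating complex, had a log2 fold change of 2.03 that did not pass (adjusted p = 0.310). Outside the list, the alpha-2A adrenoceptor gene Adra2a (-2.95), Siglech (-1.94), a receptor of plasmacytoid dendritic cells, the death ligand gene Tnfsf10 (-1.88), Pik3ip1 (-1.83) and Rasd2 (-1.81) fell.

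**Figure D3:**
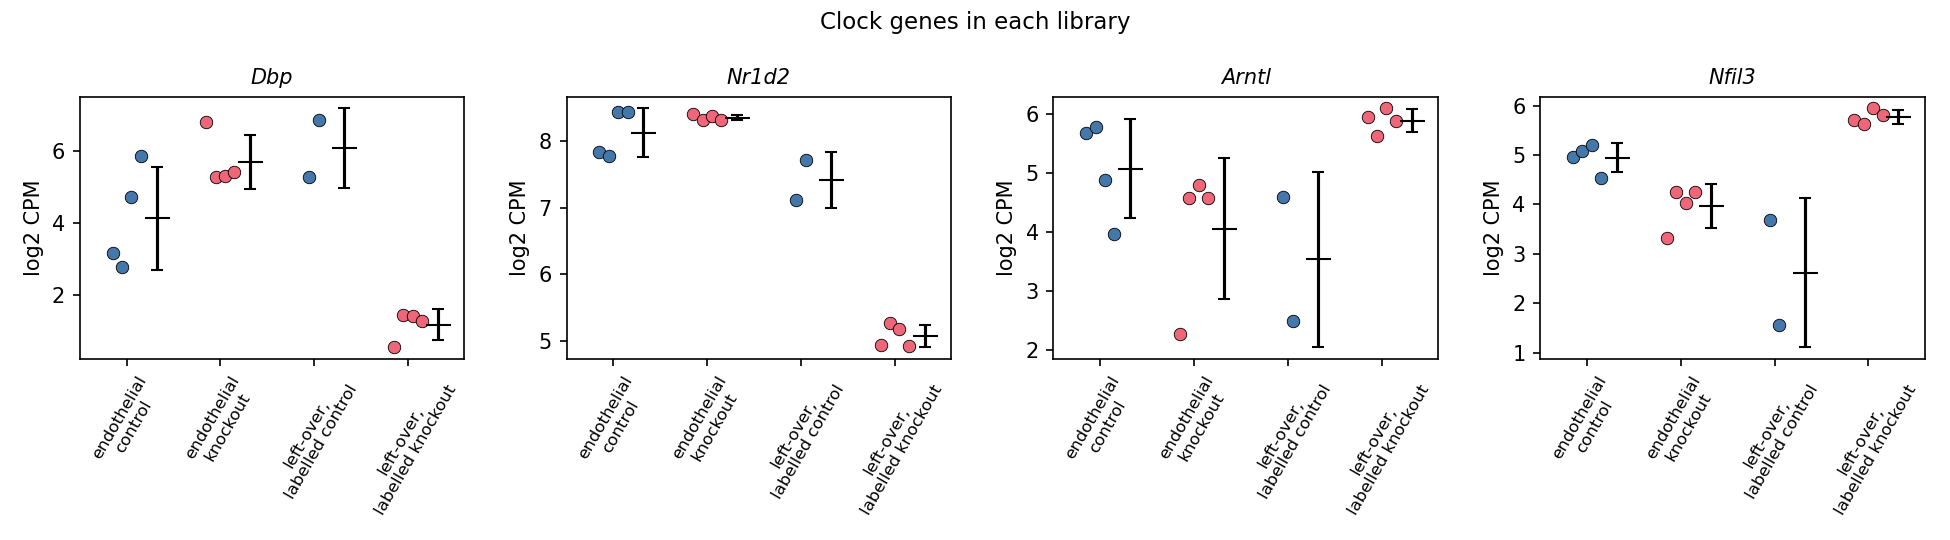
Log2 CPM (vertical axes, not starting at 0) of 4 genes of the circadian clock and its output in each library, 1 point per library, with the mean and 1 SD of each group. Dbp and Nr1d2 are lower in the 4 left-over libraries labelled knockout than in both labelled control, and the endothelial controls differ from each other in Dbp.

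**Figure D4:**
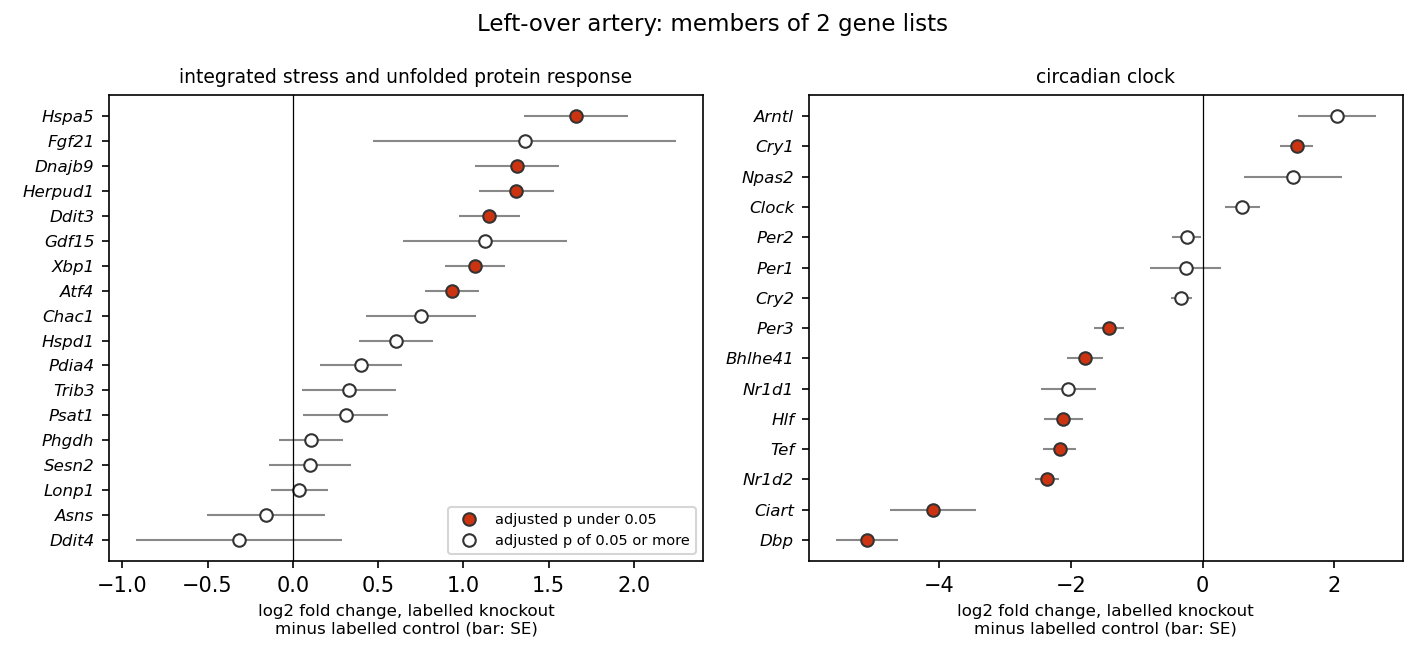
Log2 fold change of left-over labelled knockout minus labelled control (horizontal axis, bars 1 SE) for each member of the stress response list and the circadian clock list. Filled points passed at an adjusted p under 0.05 by edgeR, 6 of 18 and 8 of 15 members.

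Some lists of cell type markers were called by camera as well. By the exact permutation test of the list scores, p was 0.267 for endothelial markers, 0.2 for junction genes, 0.333 for adipocyte markers and 0.2 for erythroid markers. It was 0.0667 for the extracellular matrix list, the smallest possible. Endothelial markers were lower in the libraries labelled knockout (median -0.62, 18 of 20 negative; camera adjusted p = 2.1e-04; 0.824 with an estimated correlation), as were endothelial junction genes (median -0.28; 0.0186; 0.824 with an estimated correlation) and adipocyte markers (median -0.996, 11 of 12 negative; 7.7e-04; 0.824 with an estimated correlation). Erythroid markers were higher, 8 of 8 positive with a median of 1.09 (7.7e-04; 0.824 with an estimated correlation). The extracellular matrix list was lower (median -0.25; 0.00205; 0.824 with an estimated correlation), and its collagen gene Col8a1 (-1.24) was the 1 member called in these 5 lists, both over all genes and adjusted over the list alone. Without labelled control 1 the adipocyte, erythroid and matrix calls ended, and the junction call ended without labelled control 2 and without labelled knockout 2 or 3. Smooth muscle contractile genes had a median of -0.09 and were not called (0.216).

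In all, edgeR called 162 of 20442 genes, 86 higher and 76 lower in the libraries labelled knockout, 104 of them by more than a log2 fold change of 1. The count was 65 without labelled control 1, 41 without labelled control 2, 86 without labelled knockout 1 and 260 without labelled knockout 4. The calls of Hsph1, Spon2, Manf, Hspa5, Dbp, Ciart, Hlf, Siglech, Tnfsf10 and Rasd2 each ended in at least 1 omission of a library, with adjusted p of up to 0.0934, 0.0950, 0.0556, 0.137, 0.104, 0.293, 0.0736, 0.246, 0.227 and 0.464 in that order. Those highest values came without labelled knockout 2 for Dbp and Ciart, labelled knockout 4 for Manf and Hspa5, labelled control 1 for Siglech and labelled control 2 for the rest. Of the 6 omissions, 5 ended the call of Ciart, 4 those of Hspa5 and Siglech, 3 those of Hsph1, Dbp and Rasd2, and 1 each of the rest. With all 14 samples in one fit and the clock phase score as a covariate edgeR called 0 genes. That score contains Dbp, itself called, and separates the labelled left-over groups, so this loss of calls decides nothing. In the left-over libraries alone 350 were called by DESeq2, 397 without a low-count filter and 2015 with the replicate number as a block. The authors' deposited table called 513 genes between its smooth muscle groups, 301 higher and 212 lower, and 149 of the 162 were among them. Its log2 fold changes correlated with those here at r = -0.841 across 20442 genes, with Poldip2 at -1.25, Dbp at 3.82, Hspa8 at -1.82 and Spon2 at -1.49.

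The last comparison asked whether the labelled knockout effect differed between the fractions, as endothelial effect minus left-over effect. Fraction and mouse line cannot be separated in it, since each line was sampled in 1 fraction. The clock phase differences between the groups of both fractions enter it as well. Clock genes called under the labels had higher differences, with Ciart at 5.48, Bhlhe41 at 2.61, Nr1d2 at 2.57 and Tef at 2.33. With the left-over labels exchanged, these were -2.73, -0.99, -2.17 and -2.05, of which that of Nr1d2 passed (adjusted p = 0.00331). Spon2 had the lowest difference under the labels, -4.39, being -2.11 in the endothelial and 2.31 in the left-over comparison, and 0.19 with the labels exchanged. Poldip2 itself differed by -2.15 (adjusted p = 0.00175).

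By list, the clock had 4 genes with a higher difference and 0 lower of 15 (median 1.88; camera adjusted p = 1.0e-04; 0.241 with an estimated correlation), and 9 higher and 3 lower adjusted over the list alone. The stress response list had 0 higher and 2 lower of 18, Ddit3 (-1.33) and Atf4 (-1.10) (median -0.78; 3.9e-05; 0.241 with an estimated correlation), and 6 lower adjusted over the list alone. Smooth muscle contractile genes had a median difference of 0.57 (1.0e-04; 0.241 with an estimated correlation) with Myh11 (2.15) called, and 2 genes adjusted over the list alone. The other 9 called lists had no called member. Endothelial markers (median 0.72), endothelial junctions (0.38), adipocyte markers (2.11), lipoylation and TCA cycle genes (0.23), oxidative phosphorylation subunits (0.22) and autophagy genes (0.16) had positive medians. Fibroblast (-0.66), erythroid (-1.19) and mitochondrially encoded genes (-0.74) had negative ones, and these 9 lists had an adjusted p of 0.555 with an estimated correlation. Of the 9, 7 lost their call in at least 1 omission. Their highest adjusted p was 0.808 for oxidative phosphorylation and for lipoylation, and 0.146 for adipocyte and for erythroid markers, without labelled control 1. It was 0.121 for mitochondrially encoded genes and 0.0513 for fibroblast markers without labelled control 2, and 0.165 for autophagy without endothelial control 2. Dnajb1 (-1.79) was the single called gene of the immediate early list.

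In all, edgeR called 55 of 21464 genes, 32 with a higher and 23 with a lower difference. The other named genes were Susd5 (2.61), Pik3ip1 (2.21), Ehhadh (2.18), Fam214a (1.70), Gpcpd1 (1.66), Nfil3 (-3.78), Stk32a (-3.41), Mthfd2 (-2.61), Banp (-2.26), Arsi (-2.07), Ephb2 (-1.87) and Pkdcc (-1.69). The count was 7 without endothelial control 1, 11 without endothelial control 2, 7 without endothelial control 3, 94 without endothelial control 4, 131 without endothelial knockout 1, 20 without endothelial knockout 4, 18 without labelled control 1, 7 without labelled control 2, 32 without labelled knockout 1 and 105 without labelled knockout 4. The calls of Poldip2, Nr1d2 and Spon2 withstood the omission of any 1 library. Each other gene named by the rule lost its call without at least 1 library, with a highest adjusted p between 0.0557 for Stk32a, without labelled control 2, and 0.215 for Ehhadh, without labelled control 1, where its difference was 1.41. Without labelled control 2 that of Ciart was 3.59 and that of Bhlhe41 1.99, and Nfil3 ran from -5.19 without labelled control 1 to -3.07 without labelled control 2. With the clock phase score as a covariate 1 gene was called, but that score contains Dbp and separates the labelled left-over groups. With the library code as a random block in limma voom 43 genes were called, the difference in Poldip2 was -2.17 (adjusted p = 0.00143), and Ciart, Bhlhe41, Susd5, Ehhadh, Arsi and Ephb2 did not pass. With the left-over labels exchanged, 3 genes were called and the difference in Poldip2 was 0.40 (adjusted p = 0.781).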

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

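The tests of the exchanged labels, of 1 wrong label, of correct labels, of the clock phase, of cell makeup, of Poldip2 deletion and of the splits of the endothelial libraries were chosen only after the result was seen, the bound of the clock phase test was tightened after its first outcome, and the cell makeup test took the place of earlier forms whose outcomes had been seen.

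Poldip2 differed between the fractions in its labelled knockout effect by -2.15 on the log2 scale, being -0.89 in the endothelial fraction and 1.29 in the left-over libraries labelled knockout. A single wrong label would need the difference to vanish without that library, but the lowest of the 6 left-over values with 1 library omitted was 1.17. The deposited smooth muscle control mean equalled the mean of the 4 libraries labelled knockout in 100% of genes at 1 FPKM or more, so an exchange of the group labels of the left-over libraries may be the source. Correct labels with a knockout that raised Poldip2 RNA cannot be told apart from it, since misnamed deposited groups would give the same match. That match also fixes the share of genes matching the deposited knockout mean at 0%. In 0 of 30611 genes did 4 times that knockout mean fall below the sum of both libraries labelled control. For each other library it fell below in 2.94 to 8.44% of genes. Misnamed groups would give this too. Of the library codes, 3 also occur both among the endothelial controls and among the left-over libraries labelled knockout, and whether a code stands for 1 mouse is not stated.

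Clock genes were called in the left-over comparison, 8 of 15, and Ciart, Bhlhe41, Nr1d2 and Tef differed between the fractions by 5.48, 2.61, 2.57 and 2.33 under the labels. A different makeup of cell types, as the whole source, is argued against for the 11 marker lists taken 1 at a time: with each list's score as a covariate all 7 genes called lower kept a 95% interval under 0 and a median of -2.68 to -2.02 (median absolute deviation 0.42 to 0.98) against -2.17 (0.57), though only 3 to 7 stayed called, each ended call having a larger SE than before. A different clock phase, such as another time of day at collection, may be the source and stays open. The left-over differences correlated across the 15 clock genes at r = 0.880 with the differences of endothelial controls 1 to 3 from control 4. However, the other splits of the 4 endothelial controls gave an absolute r of up to 0.933, so the r is not specific to that split. The lowest absolute r over the 7 splits was 0.521, so controls of 1 genotype varied along a similar pattern of clock genes. The clock phase score was -5.38 to -4.17 in the libraries labelled knockout and 0.70 and 4.37 in those labelled control, and collection times are not given in the sources used here. Deletion of Poldip2 cannot be told apart from a clock phase difference for the 8 called clock genes, because the clock score and the labelled groups coincide. The same holds for the other genes called in the left-over comparison, those of the stress response list among them.

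Endothelial and left-over fold changes correlated across 11405 genes at r = -0.189 (Spearman's rank coefficient -0.200) under the labels, and of 142 genes with an unadjusted p under 0.05 in both, 97 (68.3%) had opposite signs. With the left-over labels exchanged r would be 0.189 and 45 (31.7%) would have opposite signs. A chance arrangement of the endothelial libraries stays open, since 38 of 70 arrangements gave an r as far from 0 (exact p = 0.543), up to 0.390. With the clock phase score as a covariate in the endothelial fit r was 0.0737, which lay between the bounds set for a shared clock phase and against it. A shared clock phase cannot be told apart from other sources by that value, and no biological explanation was tested.

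In the endothelial comparison the real count was 0, so that all 35 splits of the 8 libraries into 4 and 4 necessarily gave at least as many. The highest other gave 2, and the splits decide nothing about chance there. In the left-over comparison the 15 splits are too few for a share under 0.05. The real split gave 162 genes, 1 split gave as many, itself, and the highest other gave 28.

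By a test of the difference itself, 55 genes and 12 lists differed between the fractions in the labelled knockout effect. Of the 12 lists 0 held with an estimated correlation and 2 by fry. DESeq2 called 421 genes, and with the left-over labels exchanged edgeR called 3, so the directions below hold under the labels. Besides those above, the differences were 2.61 for Susd5, 2.21 for Pik3ip1, 2.18 for Ehhadh, 2.15 for Myh11, 1.70 for Fam214a and 1.66 for Gpcpd1. They were -4.39 for Spon2, -3.78 for Nfil3, -3.41 for Stk32a, -2.61 for Mthfd2, -2.26 for Banp, -2.07 for Arsi, -1.87 for Ephb2, -1.79 for Dnajb1 and -1.69 for Pkdcc.

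Libraries far from the rest of their group were sought in 270 values of groups of 4, by the gap to the nearest library as a share of the range, against Dixon's 95% critical value. There were 21 such values (7.78%), and chance gives about 1 in 20. Endothelial knockout 1 stood apart in 10 of the values. Its macrophage list was 4.71 in mean log2 CPM against 0.782 to 1.39 in the other knockouts (share 0.845), and its NADPH oxidase and antioxidant list 5.04 against 4.39 to 4.44 (0.926). In log2 CPM it was low in Hsph1 (4.88 against 7.13 to 7.49; 0.864), Hspa8 (9.43 against 11.2 to 11.4; 0.905), Mycn (0.978), Nrarp (0.933) and Sdcbp2 (0.991). It was high in Dbp (6.80 against 5.27 to 5.41; 0.907), Hlf (0.908) and Igsf10 (0.852). Endothelial knockout 4 was low in Stk32a (0.840).

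Among the left-over libraries labelled knockout, library 1 had a mitochondrial share of 0.951% against 0.377 to 0.466% (share of the range 0.845) and a mitochondrially encoded list of 6.66 against 5.44 to 5.58 (0.882). It was also low in Dbp (0.833) and in Pkdcc (0.870). Library 2 was low in Dnajb1 (0.835). Library 3 was low in the smooth muscle list, 7.09 against 7.22 to 7.23 (0.949), and in Otogl (0.905), and high in the neighbours of Poldip2, 2.63 against 2.16 to 2.19 (0.923). Library 4 was high in the NADPH oxidase and antioxidant list, 5.77 against 5.64 to 5.65 (0.956), and in Adra2a (0.848).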

How the results depend on the processing

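The exchanged left-over labels, the fibroblast and clock phase covariates and the omission of the 2 endothelial libraries highest in fibroblast markers were chosen after seeing the data. The cause of the changes below was not tested, except that omissions leave fewer samples and that the exchanged labels turn the left-over directions by construction.

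In the endothelial comparison, edgeR called 14 genes without a low-count filter, 4 with all 14 samples in one fit, 113 with the fibroblast score as a covariate, 3 with the clock phase score and 97 without both fibroblast-rich libraries, against 0, and DESeq2 called 69. Omission of 1 library gave 0 to 20 genes, 20 without knockout 1 and 1 without control 4. Poldip2 passed with DESeq2 (-0.88; adjusted p = 5.3e-04), with the clock phase score (-1.17; 0.0151), without both fibroblast-rich libraries (-1.07; 0.00659) and without knockout 1 (-1.05), and ran from -1.05 to -0.80 with 1 library omitted. Without both fibroblast-rich libraries, the fibroblast score and the genotype coincided. Macrophage markers were higher, not lower, with the fibroblast score (adjusted p = 0.00323). Of the 7 lists called, 0 held with an estimated correlation and 0 by fry, and omissions gave 5 to 10. The other settings tried for lists were the block, the smooth muscle, fibroblast and clock phase scores, and omission of both fibroblast-rich libraries. Together with the estimated correlation and fry, 26 calls of the 7 lists held, 22 ended and 1 reversed.

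In the left-over comparison the count of 162 became 397 without a filter, 350 with DESeq2, 2015 with the replicate number as a block, 59 with the adipocyte score and 0 in the fit of all 14 samples with the clock phase score, and 41 to 260 with 1 library omitted. The block rests on the 2 numbers both groups share. Poldip2 was 1.82 with the clock phase score (adjusted p = 0.110) and -1.29 with the labels exchanged, and 1.17 to 1.41 with 1 library omitted, ending without labelled control 2. Hlf was 0.67 with the clock phase score (0.985). That score contains Dbp and separates the labelled left-over groups, so the results with it decide nothing about the source. Against 7 lists, 12 were called with the block, 11 with the clock phase score, 0 with an estimated correlation, 0 by fry, and 6 to 12 with omissions. The larger totals do not mean that the same 7 lists held. Over the block, the clock phase score, the estimated correlation and fry together, 8 calls of the 7 lists held and 20 ended. Some of those 20 ended with the block or the clock phase score.

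Between the fractions the count of 12149 stayed within 1.5 times under every alternative run, 9098 to 12744 with 1 library omitted, and of the 12 lists called 0 held with an estimated correlation and 12 were among the 16 called by fry, with 10 to 13 called with omissions. For the difference of effects the count of 55 became 421 with DESeq2, 19 with the block, 1 with the clock phase score, 43 with the library code as a random block, 3 with the labels exchanged and 7 to 131 with 1 library omitted. Poldip2 differed by 0.40 with the labels exchanged and by -2.34 to -2.03 with omissions. The exchanged labels also reversed Ciart (-2.73), Bhlhe41 (-0.99), Nr1d2 (-2.17), Tef (-2.05), Pik3ip1 (-1.49), Ehhadh (-1.41), Fam214a (-1.02), Gpcpd1 (-0.62), Spon2 (0.19), Nfil3 (1.85), Mthfd2 (1.98), Banp (1.33), Dnajb1 (0.65) and Pkdcc (0.69), of which Nr1d2 passed. Of 12 lists, 0 held with an estimated correlation and 2 by fry, the clock and the stress response, and omissions gave 8 to 14. Over the estimated correlation, fry, the block and the clock phase score together, 18 list calls for the difference of effects held and 30 ended. The sex covariate was not run, as 14 of 14 libraries were male. At 15019891 to 23287155 counts, 3 counts in a library are 0.129 to 0.1997 CPM, the upper limit that a count of 0 allows.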

Other observations

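The list tests below were planned, and the members named in them were chosen after their values were seen.

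Genes of vascular tone divided between the fractions in the libraries labelled control. Of 18 vasoactive and shear-responsive genes, 12 were higher in the flushed fraction and 5 lower (median 2.19; camera adjusted p = 0.0963), and 12 and 6 adjusted over the list alone. Edn1 (5.19), Ece1 (3.85), which encodes the enzyme that processes endothelin, Klf2 (3.19), a shear-responsive transcription factor, and Gch1 (2.85), which makes the cofactor of nitric oxide synthase, were higher. The endothelin receptor genes Ednra (-4.34) and Ednrb (-3.56), the soluble guanylate cyclase subunits Gucy1b3 (-3.94) and Gucy1a3 (-3.73) and the angiotensin receptor Agtr1a (-2.91) were lower. Matrix genes divided too, with 8 of 21 higher and 7 lower (median -0.04; 0.987). Fn1 (2.43), Col4a1 (2.27), Col8a1 (2.23) and Eln (2.03) were higher in the flushed fraction, and Col15a1 (-4.59), Timp1 (-4.04), Col6a1 (-3.50) and Loxl1 (-3.16) were lower.

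Among oxidase and antioxidant genes, Nox4 (-3.25), the oxidase that Poldip2 is known to bind, Ncf1 (-3.95), Hmox1 (-3.23) and Cybb (-3.13) were lower in the flushed fraction, and Gclm (1.56), of glutathione synthesis, was higher. Interferon response genes had 8 of 18 higher and 1 lower (median 0.75; 0.197), with Igtp at 1.72. Cell cycle and DNA replication genes had 8 of 20 higher and 1 lower (median 0.69; 0.197), with the helicase gene Mcm2 at 1.30 and the polymerase gene Pold1 at 1.23, and 7 and 1 adjusted over the list alone. Glycolysis and hypoxia genes had 5 of 18 higher and 8 lower (0.473), and autophagy genes 7 of 17 higher and 6 lower (0.987; median 0.07, direction of the test down). Clock genes had 5 of 15 higher and 2 lower (0.492), and 3 and 2 adjusted over the list alone. Stress response genes had 5 of 17 higher and 4 lower (0.582), with a median of 0.60 and a mean of -0.03. Lipoylation and TCA cycle genes had 8 of 22 lower and 0 higher (0.123).

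Other cell types gave fewer called members between the libraries labelled control of both fractions. Lymphocyte markers had 1 of 11 higher and 4 lower in the flushed fraction (camera adjusted p = 0.180), platelet and neutrophil markers 5 of 11 lower (0.0963), skeletal muscle markers 4 of 8 lower (0.197), and Schwann and neuronal markers 2 of 9 higher and 2 lower (0.987). Erythroid markers had 0 of 7 called (0.987). The neighbours of Poldip2 had 2 of 11 higher and 4 lower (0.320), mitochondrially encoded genes 3 of 13 higher and 2 lower (0.704), and sex genes 2 of 4 higher, without a list test. Adjusted over the list alone, 3 lymphocyte, 4 platelet and neutrophil, 2 skeletal muscle and 1 of the Schwann and neuronal markers were lower, and the other counts of these lists were the same.

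In the left-over comparison, adjusted over the list alone, 4 of 18 interferon response genes were lower in the libraries labelled knockout (median -0.12; camera adjusted p = 0.0968), among them Ifit3 (-1.34). So were 3 of 18 glycolysis and hypoxia genes, whose median was 0.04 and whose mean was -0.19 (0.216). They were Pfkfb3 (-1.03), Bnip3 (-0.74) and Hif1a (-0.49). Of the 20 oxidase and antioxidant genes 1, Nox4 (-0.67), was lower adjusted over the list alone, and the list was not called (0.887). No member of these 3 lists was called over all genes. The neighbours of Poldip2 had a median of 0.21 there (0.592) and -0.08 in the endothelial comparison (0.526), so the genes beside Poldip2 on chromosome 11 were not called in either.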
